A study of Mus musculus with 51 samples.

How the data were processed

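Lungs of male C57BL/6 mice that had received saline or bleomycin through the trachea were sampled at day 14 and sorted by flow cytometry into 4 fractions. These were EpCAM+ (epithelial), CD45+ (leukocyte), CD31+ (endothelial) and triple-negative cells, which lack all 3 markers and hold fibroblasts and other mesenchymal cells. The design text gives 5 saline and 8 bleomycin animals. RNA was extracted with an RNeasy kit and sequenced from stranded total RNA libraries, 1 per animal and fraction. Of 51 libraries, 12 were CD31+ (7 bleomycin, 5 saline) and 13 came from each other fraction (8 bleomycin, 5 saline). Groups were taken from the labels, and single libraries are called by their label, which joins treatment, fraction (Negative for triple-negative) and replicate number. Replicate numbers differ between fractions, so which libraries came from 1 animal was not given in the sources used here, and libraries were treated as independent. By these animal numbers the fractions share animals, so libraries of different fractions are not all independent.

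The values are read counts per gene, which the authors deposited as 1 table and as 51 files, 1 per library. All 51 matched the table count for count. Counts were whole numbers for 36528 NCBI Entrez gene identifiers, of which 30717 had a count in at least 1 library. The genome build is GRCm38 per the labels. The aligner, the counting program, the annotation and the strand setting were not given in the sources used here. Symbols and positions came from the RefSeq annotation of GRCm38.p6 for 31049 identifiers, and symbols for another 76 from GENCODE M21. The remaining 5403 identifiers had no symbol and held 1.58% of all counts. No library name was contradicted by the name table among the deposited files (0 of 51).

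Totals ran from 15.7 to 36.5 M counts (M, mega; median 22.7 M). The fit was tried on simulated counts with these depths and replicate numbers. Their spread was set by a formula and not estimated from these libraries. In each fraction 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold, drawn from genes above a minimum mean count. These are far fewer than were called in the real comparisons, so the shares describe the simulation and not the precision of those comparisons. With changes placed into simulated counts at the depths and group sizes used here, 89.6%, 86.6%, 94.0% and 83.6% of genes changed 2-fold were recovered in CD31+, CD45+, EpCAM+ and triple-negative libraries. For 1.5-fold changes the shares were 37.3%, 34.3%, 29.9% and 25.4%, and for 4-fold changes 100%. Of 200 genes changed 2-fold in 1 fraction only, 96 were recovered by the test of a difference between fractions. A list of genes shifted together was called (adjusted p = 3.2e-21), and 0 of 20 unshifted lists were. Simulated genes varied independently of each other, so this trial says nothing on lists whose members vary together.

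Within each fraction, genes with low counts were removed by filterByExpr, libraries were scaled by TMM factors, and bleomycin was compared with saline by the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion, in R 4.3.3. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes of a fraction, and an adjusted p under 0.05 counted as past the threshold. Standard errors (SE) are the size of the log2 fold change divided by the square root of F. Counts scaled to a total of 1 M (CPM) are given as mean ± SD over libraries, on TMM-scaled library sizes. For genes within a fraction the TMM factors are those of that fraction. Where fractions are set beside each other, and for single levels of Epcam and Col1a1, they are those of all 51 libraries. One fit of all 51 libraries tested whether the effect of bleomycin differed between fractions, with 1 F test over the 3 interaction terms and 1 contrast per pair of fractions. P-values for single genes measure the spread between these libraries, which the fits take as independent. Those of camera, used for gene lists, compare list members with other genes under an assumed correlation between members.

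50 gene lists (725 genes, of which 8 were not found by symbol) were written before the data were examined, as were the comparisons, the rule for naming genes and the first set of alternatives. Lists with at least 3 measured members were tested by camera of limma 3.58.1 with its preset correlation of 0.01, adjusted over the lists of a fraction. Each was tested again with an estimated correlation and by fry, whose p tests whether the members move on balance in 1 direction and does not compare them with other genes. Counts "adjusted over the list alone" use the members' p-values only. Some lists share genes, such as Dcn and Col14a1 in the matrix and adventitial lists and Tnc in the matrix and fibrosis-associated lists, so list results are not independent. Lists of 12 genes each for epithelial, leukocyte, endothelial and mesenchymal cells measured sort purity as the mean log2 CPM with 0.5 added. Their group differences were tested by exact permutation tests, adjusted over 16.

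Genes were named by this rule: 23 fixed genes in every fraction. To these came the 10 largest rises and falls per fraction among genes past the threshold with at least 10 CPM in the higher group and no overlap between groups, leaving out unnamed models, pseudogenes and immunoglobulin or T cell receptor segments. Up to 4 members per described list with the smallest adjusted p were added with members that went against the list, the 10 smallest p-values of the interaction test and up to 6 genes past the threshold in opposite directions. Further list members named in the text were chosen after their values were seen. Some genes that meet the rule are not reported here.

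Alternatives were RLE and upper-quartile scaling, no filter or a stricter one (5 CPM in 5 libraries), DESeq2 1.42.0, limma voom with quality weights, robust dispersion off, 1 fit of all groups, library sizes without 84 genes of 4 classes, a leukocyte (in CD45+, epithelial) purity covariate, stricter thresholds, and leaving out each library in turn. The columns of the deposited table form 2 runs of 26 and 25 libraries, each holding every group. They were treated as a candidate batch after the data were seen, as a covariate and as separate fits within each block. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served the permutation tests and plots.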

Results

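Gene expression was compared between bleomycin and saline lungs at day 14 in 4 sorted fractions, with 7 bleomycin and 5 saline libraries of CD31+ cells and 8 bleomycin and 5 saline libraries of EpCAM+, CD45+ and triple-negative cells. Mean totals ± SD in M counts (M, mega) were 25.1 ± 2.69 (bleomycin) and 26.0 ± 2.25 (saline) in CD31+, 20.6 ± 2.15 and 19.4 ± 1.49 in CD45+, 20.9 ± 2.50 and 25.1 ± 2.40 in EpCAM+, and 22.8 ± 5.29 and 27.9 ± 5.34 in triple-negative libraries.

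Each fraction carried the gene of its sort. Pecam1, which encodes CD31, averaged 3451 CPM (bleomycin) and 3487 CPM (saline) in CD31+ libraries. In saline libraries it was 5.34 higher on the log2 scale than the mean of the other fractions (adjusted p = 2.0e-12). The contrasts of the other sort genes and of Col1a1 that follow were likewise limited to saline libraries. Ptprc, which encodes CD45, averaged 936 and 1479 CPM in CD45+ libraries (6.94 higher, 5.3e-16), and Epcam averaged 214 and 184 CPM in EpCAM+ libraries (6.22 higher, 7.7e-13). The fibroblast collagen gene Col1a1 averaged 16323 and 6555 CPM in triple-negative libraries (7.29 higher, 3.9e-16). Transcripts of other cell types were present, not all of them at low levels, and some moved with treatment. The club cell gene Scgb1a1 and the surfactant gene Sftpc had higher mean CPM in CD31+ and CD45+ libraries of either treatment than Epcam had in EpCAM+ libraries. Their own levels in EpCAM+ libraries were far higher still. Sftpc averaged 58532 (bleomycin) and 111620 CPM (saline) there, and Scgb1a1 32202 and 11278 CPM. Col1a1 reached 2348 CPM in Bleomycin_CD45_613. By exact permutation test over 12 marker genes each, the endothelial markers were lower by 1.31 on the log2 scale in bleomycin CD45+ libraries than in saline ones (difference -1.31, adjusted p = 0.0166). The fraction's own markers differed by -0.16 in CD31+ and by -0.21 in CD45+ libraries (0.0166 each). Leukocyte markers differed by 1.19 in CD31+ (adjusted p = 0.0707) and -0.73 in triple-negative libraries (0.171), and epithelial markers by 1.48 in CD31+ (0.0817) and 1.24 in triple-negative libraries (0.0796). Endothelial markers differed by -0.54 in EpCAM+ libraries (0.0817). None of these 5 passed the threshold, nor did the other 8 of 16 tests, which include all 4 of the mesenchymal markers, with adjusted p from 0.279 to 0.671. The mitochondrial share of counts ran from 0.486% to 0.689% in bleomycin and from 0.312% to 0.401% in saline CD31+ libraries. It ran from 0.512% to 1.23% and from 0.260% to 0.474% in triple-negative libraries. The groups did not overlap in either. In CD45+ (0.487% to 0.615% and 0.415% to 0.495%) and EpCAM+ libraries (1.18% to 2.40% and 1.41% to 2.14%) the groups overlapped.

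**Figure D1:**
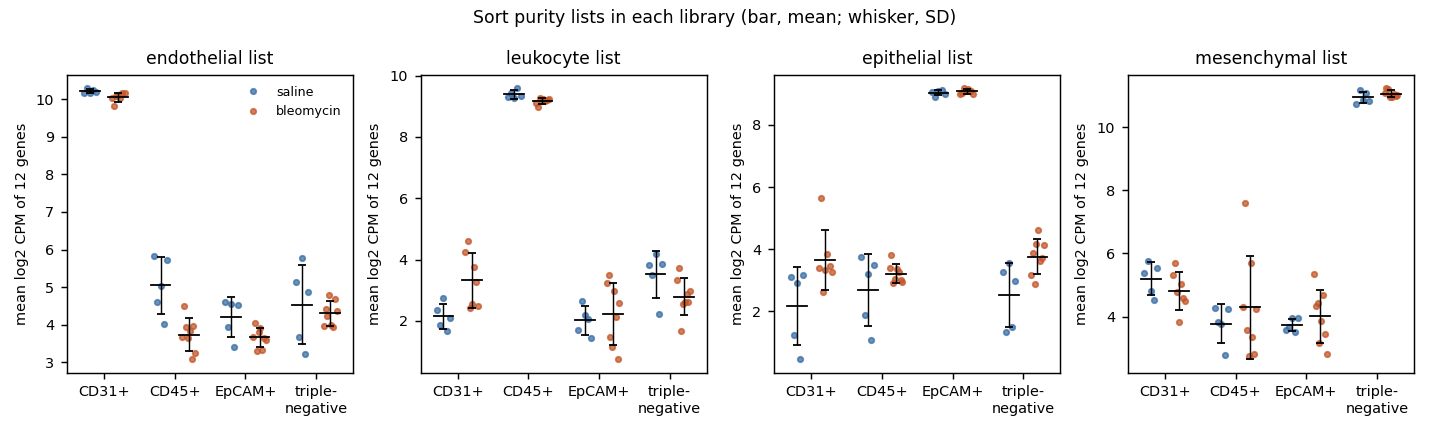
Mean log2 CPM of 12 marker genes for each of 4 cell types (vertical axis) in each library, by fraction and treatment, with bars at the group mean and whiskers of 1 SD. Each fraction is highest in its own markers, and endothelial markers in CD45+ libraries are lower after bleomycin (difference -1.31).

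In CD31+ cells, the question was which endothelial genes change after bleomycin. Under the preset correlation of the list test, genes of cell division, lymphatic endothelium and monocyte-derived macrophages rose as groups. Those of general capillary endothelium, of the interferon response and the immediate early genes, which react to stress within minutes, fell as groups. None of these calls held with an estimated correlation (adjusted p = 0.958 for each with an estimated correlation).

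Of 16075 genes tested in CD31+ libraries, 3890 were higher and 3948 lower after bleomycin by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1137 and 713 of them by at least 2-fold. In 4243 genes (26.4%) the groups did not overlap, where chance gives 0.253%. Top2a, the DNA topoisomerase of dividing cells (Entrez 21973, GRCm38 chromosome 11, 98992947 to 99024199), rose from 5.65 ± 0.87 CPM (SD, n = 5) to 136 ± 46.7 CPM (n = 7), a log2 change of 4.59 ± 0.28 (SE, adjusted p = 1.8e-06). The proliferation marker Mki67 rose by 4.40 (1.8e-06). The mitotic genes Ckap2, Pbk, Melk, Nuf2 and Pimreg rose by 4.63 to 4.91. Of the other largest rises, Mmp12 (a macrophage elastase), Retnla (a secreted product of alternatively activated macrophages and airway epithelium), Spp1 (osteopontin) and Tnc (the matrix protein tenascin C) rose by 6.90, 5.88, 5.34 and 4.68. Fn1, which encodes fibronectin, rose by 2.75 (5.6e-04). The largest falls were in the platelet genes Tubb1 (-4.77) and Ppbp (-4.30), and Actc1, Fam71a, Iqcn and Ankrd63 changed by -3.24 to -2.64. Esm1, a marker of endothelial tip cells, fell by 2.94 (5.4e-06), and the smooth muscle genes Myh11 (-2.51) and Acta2 (-1.86) fell too. Pecam1 (-0.03, adjusted p = 0.705), the von Willebrand factor gene Vwf (-0.27, 0.0736) and the capillary gene Car4 (-0.30, 0.157) did not pass the threshold, but Vwf did without Bleomycin_CD31_624 (-0.33, 0.0364) or Saline_CD31_649 (-0.34, 0.0412). The keratin gene Krt8 passed it (1.69, 0.0365) but not without Bleomycin_CD31_621, Bleomycin_CD31_624, Saline_CD31_650, Saline_CD31_651 or Saline_CD31_652 (adjusted p 0.0539 to 0.0811).

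By list, 29 of 30 cell cycle genes rose in CD31+ libraries and 0 fell (30 and 0 adjusted over the list alone; median 3.69, camera adjusted p = 1.3e-15, adjusted p = 0.958 with an estimated correlation). In lymphatic endothelium 6 of 7 rose (6 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.958 with an estimated correlation), led by the lymphatic regulator Prox1 (2.51) with Mmrn1 (2.20), Thy1 (2.10) and Reln (2.04), while the hyaluronan receptor gene Lyve1 fell (-0.65). In the general capillary endothelium list 5 of 10 fell, among them the caveolar diaphragm gene Plvap (-0.91), Ptprb (-0.74) and the angiopoietin receptor gene Tek (-0.65), and Nostrin rose (0.35), with the same counts adjusted over the list alone (adjusted p = 0.0417, and adjusted p = 0.958 with an estimated correlation). That call was lost without Bleomycin_CD31_626, Saline_CD31_650 or Saline_CD31_652 (0.0548 to 0.0703) and with the purity covariate (0.0663). The interferon response list had 19 of 29 lower and 3 higher, the same adjusted over the list alone (0.00806, and adjusted p = 0.958 with an estimated correlation): the antiviral genes Mx2, Gbp3 and Gbp2 fell (-1.18, -0.99 and -0.88), and Oas3, Mx1 and Ifi27l2a rose by 1.83, 1.31 and 1.05. Immediate early genes fell in 16 of 20 and rose in 0, the same adjusted over the list alone (2.0e-05, and adjusted p = 0.958 with an estimated correlation).

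Metabolic and matrix lists rose in part in CD31+ libraries. For lipid and sterol synthesis 10 of 16 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.00806, and adjusted p = 0.958 with an estimated correlation), with the fatty acid enzymes Scd1 (2.76) and Fasn (1.58) up and the sterol sensor partner Insig1 down (-0.58). In glycolysis and hypoxia 11 of 19 rose and 2 fell (12 and 2 adjusted over the list alone; 0.0325, and adjusted p = 0.958 with an estimated correlation; 0.0652 without Saline_CD31_652). Ankrd37 (2.87) and the hexokinase gene Hk2 (1.48) rose, and the angiogenic growth factor gene Vegfa (-0.53) fell. Gapdh (-1.49) fell as well, at an unusually low level that makes it uncertain. Whether reads shared with its pseudogenes play a part was not tested. In basement membrane 11 of 20 rose and 3 fell (11 and 4 adjusted over the list alone; 0.0409, and adjusted p = 0.958 with an estimated correlation), a call lost without Bleomycin_CD31_621 (0.0814) or Saline_CD31_652 (0.0782). The collagen IV genes Col4a1 and Col4a2 rose by 1.36 and 1.43 and Col18a1 by 2.14, while the laminin genes Lama2, Lama3 and Lama5 fell.

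Transcripts of other cell types moved in CD31+ libraries as well. Of 23 genes of the monocyte-derived macrophage list 18 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.00206, and adjusted p = 0.958 with an estimated correlation), beside leukocyte markers 1.19 higher. The rise of those 18 amounted to a median of 3.62% of their level in bleomycin CD45+ libraries. Of 12 epithelial purity genes (list name: epithelial, for sort purity) 4 rose (9 adjusted over the list alone; 0.0409, and adjusted p = 0.958 with an estimated correlation; lost without Bleomycin_CD31_623, Saline_CD31_650 or Saline_CD31_652, 0.0561 to 0.088). Without Bleomycin_CD31_621, whose epithelial markers stood apart, 0 of the 12 rose, with the purity covariate 0 and with the block covariate 11. Of 18 genes of the alveolar type II and surfactant list 6 rose (0 adjusted over the list alone; 0.046, and adjusted p = 0.958 with an estimated correlation; lost without Bleomycin_CD31_620, Bleomycin_CD31_621, Bleomycin_CD31_623, Saline_CD31_650 or Saline_CD31_652, 0.0504 to 0.09). Without Bleomycin_CD31_621 2 of these 18 rose and 1 fell. With the purity covariate 0 rose and 1 fell, and the list pointed down (adjusted p = 0.892). With the block covariate 14 rose.

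Within the first column block (3 bleomycin, 3 saline) 1678 genes were higher and 1501 lower in CD31+ libraries, within the second (4 and 2) 2186 and 2036, and with the block as a covariate 3988 and 3829. With a leukocyte purity covariate the counts were 2468 and 2395, 6 of the 11 list calls were lost (basement membrane, alveolar type II and surfactant, general capillary endothelium, glycolysis and hypoxia, lipid and sterol synthesis, and the epithelial purity genes), and without Saline_CD31_652 the number of calls was 6 in place of 11.

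In CD45+ cells, the question was how leukocyte transcripts change. Under the preset correlation, genes of monocyte-derived and resident alveolar macrophages, the cell cycle, MHC class II and complement rose as groups, and genes of NK, T and B cells and of neutrophils fell as groups. None of these calls held with an estimated correlation (adjusted p = 0.996 for each with an estimated correlation).

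Of 16493 genes tested in CD45+ libraries, 4692 were higher and 4423 lower after bleomycin, 1192 and 1395 by at least 2-fold. In 5175 genes (31.4%) the groups did not overlap, where chance gives 0.155%. Spp1 (Entrez 20750, chromosome 5, 104435111 to 104441053) rose from 20.4 ± 6.84 CPM (SD, n = 5) to 5426 ± 1415 CPM (n = 8), a log2 change of 8.05 ± 0.31 (SE, adjusted p = 5.5e-10). The lysosomal membrane gene Gpnmb rose by 5.03, the dectin-2 gene Clec4n by 4.48, the coagulation factor gene F7 by 4.68, Mmp12 by 3.26, Fn1 by 2.30, and the arginase gene Arg1 by 2.25. Cspg4, Cldn1, Syngr1 and Slc36a2 rose by 4.17 to 5.26. The largest falls included the itaconate enzyme gene Acod1 (-4.41), the decoy receptor gene Il1r2 (-3.56), G0s2 (-3.07), Miat, Vps37b and the cytokine gene Csf2 (-3.02), the histidine decarboxylase gene Hdc (-2.99), Rbpms2 and Ramp3. Endou fell by 4.60, but by 2.0 without Saline_CD45_646. The proliferation marker Mki67 did not pass the threshold (0.41, adjusted p = 0.147) but did without that library (0.80, 1.2e-04). Fibroblast transcripts in this fraction rested in part on Bleomycin_CD45_613, whose Col1a1 reached 2348 CPM. Without it the rises of Col1a1, Col3a1, Cthrc1, Tnc and Timp1 dropped from 3.77, 3.05, 3.69, 4.73 and 4.76 to 2.38, 1.74, 2.23, 3.56 and 3.84, all still past the threshold. Col3a1 and Cthrc1 also lost theirs without any 1 of the 5 saline libraries (adjusted p 0.0523 to 0.0675). Epcam rose by 2.69 (4.7e-07) and Pecam1 fell by 1.34 (1.1e-07). Ptprc fell by 0.61 (4.4e-04).

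Among leukocyte lists, 17 of 23 monocyte-derived macrophage genes rose and 1 fell, the same adjusted over the list alone (adjusted p = 1.1e-07, and adjusted p = 0.996 with an estimated correlation), with Spp1, Gpnmb, the cathepsin gene Ctsk (4.02) and the lipid receptor gene Trem2 (3.21) up and the monocyte surface gene Ly6c2 down (-1.53). In the resident alveolar macrophage list 10 of 15 rose and 0 fell, the same adjusted over the list alone (1.8e-04, and adjusted p = 0.996 with an estimated correlation), among them Atp6v0d2 (3.87), Plet1 (3.32), Chil3 (2.81) and the lectin gene Siglecf (2.22). All 12 NK cell genes fell (12 adjusted over the list alone; 1.9e-06, and adjusted p = 0.996 with an estimated correlation), among them the cytotoxic granule genes Gzma (-1.95) and Prf1 (-1.85) and the receptor gene Ncr1 (-1.73). All 10 B cell genes fell (10 adjusted over the list alone; median -1.31, 1.5e-04, and adjusted p = 0.996 with an estimated correlation). In the T cell list 15 of 17 fell, the same adjusted over the list alone (1.3e-04, and adjusted p = 0.996 with an estimated correlation), including the CD3 genes Cd3d, Cd3e and Cd3g, while Foxp3, the transcription factor gene of regulatory T cells, rose by 1.31. Of 16 neutrophil genes 8 fell and 0 rose, the same adjusted over the list alone (0.00229, and adjusted p = 0.996 with an estimated correlation), with Il1r2 and the granule genes Camp (-2.72) and Ngp (-2.05) lowest.

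Functional lists were called in CD45+ libraries as well. Of 30 cell cycle genes 16 rose and 0 fell, the same adjusted over the list alone (median 0.60, adjusted p = 1.8e-04, and adjusted p = 0.996 with an estimated correlation). In MHC class II 7 of 8 rose and H2-DMb2, which encodes a peptide-loading chaperone chain, fell by 0.50, the same adjusted over the list alone (0.0248, and adjusted p = 0.996 with an estimated correlation). In complement 7 of 14 rose and 0 fell, the same adjusted over the list alone (0.0256, and adjusted p = 0.996 with an estimated correlation; 0.0593 without Bleomycin_CD45_613), with Cfb (3.39) and C1qb (1.82) up. In lipid and sterol synthesis 10 of 16 rose and 2 fell (11 and 2 adjusted over the list alone; 0.0104, and adjusted p = 0.996 with an estimated correlation): the sterol enzymes Mvd (1.77) and Sqle (1.34) rose and the desaturase Scd1 fell (-1.01). Immediate early genes fell in 14 of 20 (15 adjusted over the list alone; 0.00155, and adjusted p = 0.996 with an estimated correlation), and the transcription factor gene Egr2 rose by 0.90. All 12 endothelial purity genes fell (12 adjusted over the list alone; 9.7e-04, and adjusted p = 0.996 with an estimated correlation).

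Within the column blocks, 3081 genes were higher and 2603 lower in the first (4 bleomycin, 2 saline) and 3553 and 3160 in the second (4 and 3) in CD45+ libraries, with 4633 and 4320 with the block as a covariate. The cell cycle list rose in 24 members in the first block and 4 in the second.

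In EpCAM+ cells, the question was how the epithelium changes. Under the preset correlation, alveolar type II genes fell, while genes of alveolar type I, ciliated, club, basal and transitional epithelial cells rose as groups (adjusted p = 0.712 to 0.774 with an estimated correlation). Interferon response, p53 target, cell cycle, matrix, protease and coagulation genes rose as groups, and immediate early, MHC class II and dendritic cell genes fell (adjusted p = 0.271 to 0.774 with an estimated correlation).

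Of 16902 genes tested in EpCAM+ libraries, 5275 were higher and 4893 lower after bleomycin, 1633 and 811 by at least 2-fold. In 6055 genes (35.8%) the groups did not overlap, where chance gives 0.155%. The surfactant gene Sftpc (Entrez 20389, chromosome 14, 70520941 to 70524081) fell from 107990 ± 5581 CPM (SD, n = 5) to 56851 ± 11523 CPM (n = 8), a log2 change of -0.93 ± 0.15 (SE, adjusted p = 7.3e-05). The cell cycle inhibitor gene Cdkn1a rose by 1.88 ± 0.13 (2.5e-08), and Psrc1, which encodes a spindle protein and is a p53 target (Entrez 56742, chromosome 3, 108383804 to 108388231), rose by 4.30 ± 0.15 (8.0e-12). The alveolar type I gene Ager rose by 0.55, the keratin gene Krt8 by 0.85, the club cell gene Scgb1a1 by 1.52, and Mki67 by 2.77. Retnla rose by 6.68, Atg9b by 6.53, the goblet cell gene Clca1 by 6.28, Spp1 by 5.37, the surface glycoprotein gene Cd177 by 4.50, Flnc by 4.44, and Fn1 by 4.30. The chitinase-like gene Chil4 averaged 32.9 CPM after bleomycin and 0.027 CPM in saline libraries, where it had too few counts for a fold. The largest falls were Hes2 (-3.86), the chemokine gene Ccl22 (-3.68), Cst8 (-3.59) and Bex2 (-3.01), followed by Iqcn, Inmt, Slc13a3, Nr4a3 and Dgkg. Tg fell by 3.58, but by 2.05 without Saline_EpCAM_658. Col1a1 (2.27) and Col3a1 (1.71) passed the threshold, the latter not without Bleomycin_EpCAM_628 or Bleomycin_EpCAM_633 or any 1 of the 5 saline libraries (adjusted p 0.0547 to 0.0776). Cthrc1 fell by 1.46 (9.0e-07), and Tgfb1 did not pass (-0.13, 0.129), but did without Saline_EpCAM_658 (-0.19, 0.0271).

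By epithelial list, 15 of 18 alveolar type II genes fell and the protease gene Ctsh rose (0.40), the same adjusted over the list alone (median -0.73, adjusted p = 4.4e-04, and adjusted p = 0.773 with an estimated correlation). Of 15 alveolar type I genes 10 rose, led by Pdpn (2.54) and the anchoring protein gene Akap5 (1.91), and the tight junction gene Cldn18 fell (-0.23), the same adjusted over the list alone (8.1e-04, and adjusted p = 0.712 with an estimated correlation). In the transitional alveolar epithelium list 20 of 23 rose, among them Cldn4 (4.05), Sprr1a (2.66), Clu (2.19) and Krt8, and the stress gene Nupr1 fell (-0.43), the same adjusted over the list alone (median 1.39, 2.5e-08, and adjusted p = 0.712 with an estimated correlation). Of 16 ciliated genes 14 rose and 0 fell (15 adjusted over the list alone; 0.00158, and adjusted p = 0.774 with an estimated correlation), with the ciliary transcription factor gene Foxj1 at 1.47. In club and secretory cells 9 of 11 rose, with the mucin gene Muc5b at 2.28, and the carbonyl reductase gene Cbr2 fell (-0.93), the same adjusted over the list alone (0.00818, and adjusted p = 0.773 with an estimated correlation). Of 9 basal and squamous genes 7 rose and 0 fell, the same adjusted over the list alone (median 1.01, 0.0152, and adjusted p = 0.712 with an estimated correlation). Krt6a, one of them, had no count in any saline library, and the median does not depend on its fold.

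Lists of cell state, defence and metabolism were called in EpCAM+ libraries as well. Of 28 interferon response genes 27 rose and 0 fell, the same adjusted over the list alone (median 1.88, adjusted p = 1.3e-11, and adjusted p = 0.647 with an estimated correlation), among them Oas3 (5.35), Isg15 (3.32) and Ifit1 (3.33). Of 30 cell cycle genes 28 rose and the checkpoint kinase gene Bub1 fell (-0.34), the same adjusted over the list alone (median 2.58, 2.5e-12, and adjusted p = 0.712 with an estimated correlation). Of 23 genes in p53 targets and senescence 19 rose, among them the death receptor gene Eda2r (4.79), the inhibitor gene Cdkn2a (4.25) and Phlda3 (3.25), and Btg2, Plk2 and Bbc3 fell, the same adjusted over the list alone (4.1e-08, and adjusted p = 0.271 with an estimated correlation). Immediate early genes fell in 16 of 20 and rose in 0, the same adjusted over the list alone (1.1e-06, and adjusted p = 0.712 with an estimated correlation). MHC class II genes fell in 6 of 8, led by H2-Eb1 (-0.73), the same adjusted over the list alone (0.031, and adjusted p = 0.774 with an estimated correlation), and lipid and sterol synthesis in 8 of 16, with Elovl6 (1.92) and Scd1 (0.46) rising, the same adjusted over the list alone (0.0337, and adjusted p = 0.774 with an estimated correlation; 0.0921 without Saline_EpCAM_654).

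Matrix-related lists rose in EpCAM+ libraries in which the Col1a1 level of the bleomycin group ran from 19.8 to 276 CPM. Of 28 genes of fibrillar and interstitial matrix 18 rose and Col16a1 fell by 0.90 (19 and 1 adjusted over the list alone; adjusted p = 0.00533, and adjusted p = 0.774 with an estimated correlation). Basement membrane genes rose in 12 of 20 and fell in 1, the same adjusted over the list alone (0.00809, and adjusted p = 0.712 with an estimated correlation), and metalloproteinases and inhibitors in 9 of 13, the same adjusted over the list alone (0.0142, and adjusted p = 0.773 with an estimated correlation). In coagulation and fibrinolysis 10 of 16 rose, with the urokinase gene Plau at 3.37, and 2 fell, with the thrombomodulin gene Thbd at -0.83 (11 and 2 adjusted over the list alone; 0.0228, and adjusted p = 0.773 with an estimated correlation). Transcripts foreign to the sort fell in part. Of 9 dendritic cell genes 8 fell, led by Ccl22, the same adjusted over the list alone (0.00428, and adjusted p = 0.712 with an estimated correlation). In the alveolar fibroblast and lipofibroblast list 7 of 11 fell and 2 rose, the same adjusted over the list alone (0.0346, and adjusted p = 0.773 with an estimated correlation). In general capillary endothelium 8 of 10 fell and 1 rose (9 and 1 adjusted over the list alone; 0.0457, and adjusted p = 0.774 with an estimated correlation), beside endothelial markers 0.54 lower on the log2 scale (difference -0.54), and this call was lost without any 1 of Bleomycin_EpCAM_628, Bleomycin_EpCAM_630, Bleomycin_EpCAM_631, Bleomycin_EpCAM_633, Bleomycin_EpCAM_634, Bleomycin_EpCAM_635, Saline_EpCAM_654, Saline_EpCAM_656 and Saline_EpCAM_658 (0.0549 to 0.0849). The first column block (4 bleomycin, 2 saline) gave 3181 higher and 2958 lower genes, the second (4 and 3) 4394 and 4045, and the block covariate 5309 and 4937.

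In triple-negative cells, the question was how fibroblasts and other mesenchymal cells change. Under the preset correlation, genes of fibrillar matrix, collagen processing and fibrosis-associated fibroblasts rose as groups, and genes of adventitial fibroblasts and pericytes fell (adjusted p = 0.737 to 0.84 with an estimated correlation). Cell cycle, interferon response and p53 target genes rose as groups, and immediate early and B cell genes fell (adjusted p = 0.619 to 0.737 with an estimated correlation).

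Of 16700 genes tested in triple-negative libraries, 4624 were higher and 4626 lower after bleomycin, 1037 and 1443 by at least 2-fold. In 4953 genes (29.7%) the groups did not overlap, where chance gives 0.155%. Cthrc1, a secreted matrix gene of activated fibroblasts (Entrez 68588, chromosome 15, 39076932 to 39087121), rose from 1.95 ± 0.61 CPM (SD, n = 5) to 93.2 ± 52.8 CPM (n = 8), a log2 change of 5.55 ± 0.54 (SE, adjusted p = 2.8e-06). The BMP antagonist gene Grem1 (Entrez 23892, chromosome 2, 113748675 to 113758648) rose by 6.0 ± 0.36 (1.1e-07). Tnc rose by 4.86 (2.2e-08), Spp1 by 5.33, Mmp12 by 5.32, the protease inhibitor gene Timp1 by 2.87, Fn1 by 2.49, the growth factor gene Tgfb1 by 1.60 (2.1e-07), Col1a1 by 1.34 ± 0.23 (1.8e-04) and Col3a1 by 1.04. Inava, Cldn4, Ptprn, Syt12, the adhesion gene Chl1 and Megf11 rose by 4.95 to 6.34. The smooth muscle actin gene Acta2 fell by 0.81 (0.0113), and the matricellular gene Postn did not pass the threshold (0.64, 0.0608), but did without Bleomycin_Negative_639, Bleomycin_Negative_642 or Bleomycin_Negative_643 (0.72 to 0.75, adjusted p 0.0193 to 0.0400). The largest falls were the chemokine genes Ccl4 (-4.75) and Ccl3 (-3.66), the calcium channel gene Cacna1e (-4.29), the B cell genes Cd79b (-3.97) and Cd79a (-3.85), the cytokine gene Il6 (-3.58), Iqcn, Myoc and the stress-induced gene Atf3 (-3.33).

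By mesenchymal list, 17 of 28 fibrillar and interstitial matrix genes rose and 4 fell in triple-negative libraries (19 and 4 adjusted over the list alone; adjusted p = 6.9e-04, and adjusted p = 0.84 with an estimated correlation), the falls being the proteoglycan genes Dcn (-1.67) and Lum (-1.19), Fbln1 (-1.16) and Col14a1 (-0.93). In collagen processing and crosslinking 13 of 20 rose and 3 fell (14 and 3 adjusted over the list alone; 0.00292, and adjusted p = 0.84 with an estimated correlation): the crosslinking enzyme gene Lox (1.44) and the hydroxylase gene P4ha3 (1.54) rose, and Pcolce2, Pcolce and Loxl4 fell. Of 14 fibrosis-associated fibroblast genes 9 rose and 4 fell (10 and 4 adjusted over the list alone; median 2.37, 0.00887, and adjusted p = 0.814 with an estimated correlation). Grem1, Cthrc1, Tnc, Adam12 (3.91) and Runx1 (2.54) rose, while Aspn (-1.71), Comp (-1.39), the surface protease gene Fap (-1.05) and Spon2 (-0.40) fell. Of 10 adventitial fibroblast genes 9 fell, among them Pi16 (-1.76), Dpp4 (-1.52) and Gsn (-1.91), and the microfibril gene Mfap5 rose (0.44), the same adjusted over the list alone (3.0e-04, and adjusted p = 0.737 with an estimated correlation). Pericyte genes fell in 7 of 9 and rose in 0, among them Notch3 (-1.33) and Higd1b (-1.88), the same adjusted over the list alone (0.0215, and adjusted p = 0.814 with an estimated correlation). The contractile myofibroblast list was not called, with 2 of 14 higher and 8 lower (3 and 8 adjusted over the list alone; 0.145).

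Cell state lists in triple-negative libraries followed. Of 30 cell cycle genes 29 rose and 0 fell, the same adjusted over the list alone (median 3.16, adjusted p = 4.4e-12, and adjusted p = 0.737 with an estimated correlation). Of 29 interferon response genes 22 rose, among them Ifi44 (2.32) and Zbp1 (2.18), and Cxcl10, Gbp2 and Ifit2 fell, the same adjusted over the list alone (1.9e-05, and adjusted p = 0.737 with an estimated correlation). In p53 targets and senescence 15 of 23 rose, among them Cdkn2a (3.88) and Psrc1 (2.57), and Btg2 and Pmaip1 fell, the same adjusted over the list alone (4.2e-04, and adjusted p = 0.619 with an estimated correlation). Immediate early genes fell in 18 of 20 and rose in 0, the same adjusted over the list alone (1.8e-07, and adjusted p = 0.737 with an estimated correlation). In lipid and sterol synthesis 9 of 16 rose and 1 fell, the same adjusted over the list alone (0.0399, and adjusted p = 0.814 with an estimated correlation; 0.0508 without Saline_Negative_662). All 10 B cell genes fell, the same adjusted over the list alone (median -3.89, 1.9e-05, and adjusted p = 0.737 with an estimated correlation), beside leukocyte markers 0.73 lower on the log2 scale (difference -0.73). Epithelial transcripts rose in part, beside epithelial markers 1.24 higher: 8 of 12 genes of epithelial, for sort purity (0.043, and adjusted p = 0.84 with an estimated correlation) rose. It was 7 of 18 in alveolar type II and surfactant with 1 lower (0.0436, and adjusted p = 0.84 with an estimated correlation), and 14 of 23 in transitional alveolar epithelium with 4 lower (0.043, and adjusted p = 0.814 with an estimated correlation), all 3 with the same counts adjusted over the list alone. Each of these 3 calls was lost without Bleomycin_Negative_639 or Saline_Negative_660 (0.0673 to 0.124), the first also without Bleomycin_Negative_640, Bleomycin_Negative_643 or Saline_Negative_662 and with the block as a covariate (0.0529 to 0.0729), the second without Bleomycin_Negative_637, Bleomycin_Negative_640, Bleomycin_Negative_643, Saline_Negative_662 or Saline_Negative_663 (0.0548 to 0.0873), and the third without Saline_Negative_661 (0.0508) or with the purity covariate (0.0532). The first column block (5 bleomycin, 3 saline) gave 3622 higher and 3482 lower genes, the second (3 and 2) 2826 and 2975, and the block covariate 4751 and 4652.

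**Figure D2:**
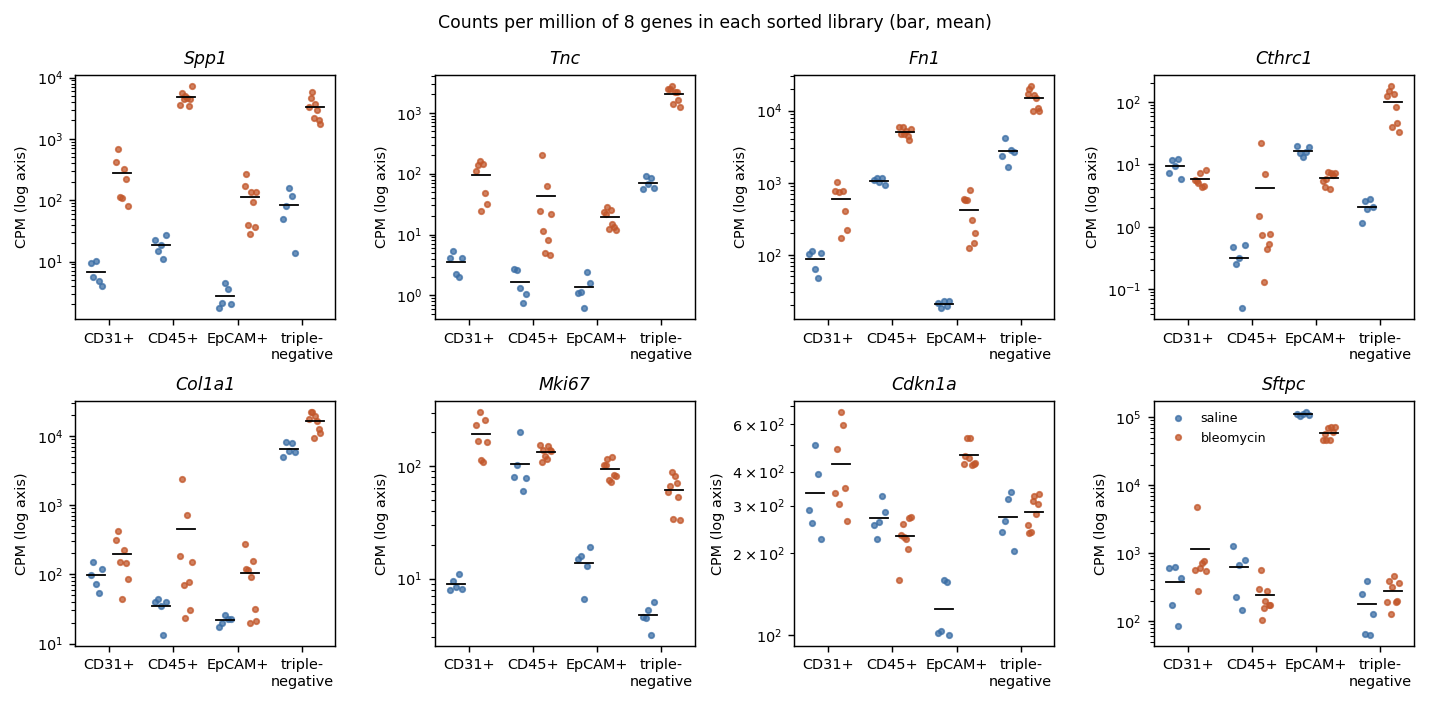
CPM (log axis) of 8 genes in every library, by fraction and treatment, with bars at the group mean. Spp1 rises in all 4 fractions, Cthrc1 rises in triple-negative and falls in EpCAM+ libraries, and Cdkn1a rises past the threshold in EpCAM+ libraries alone of the 4 fractions.

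**Figure D3:**
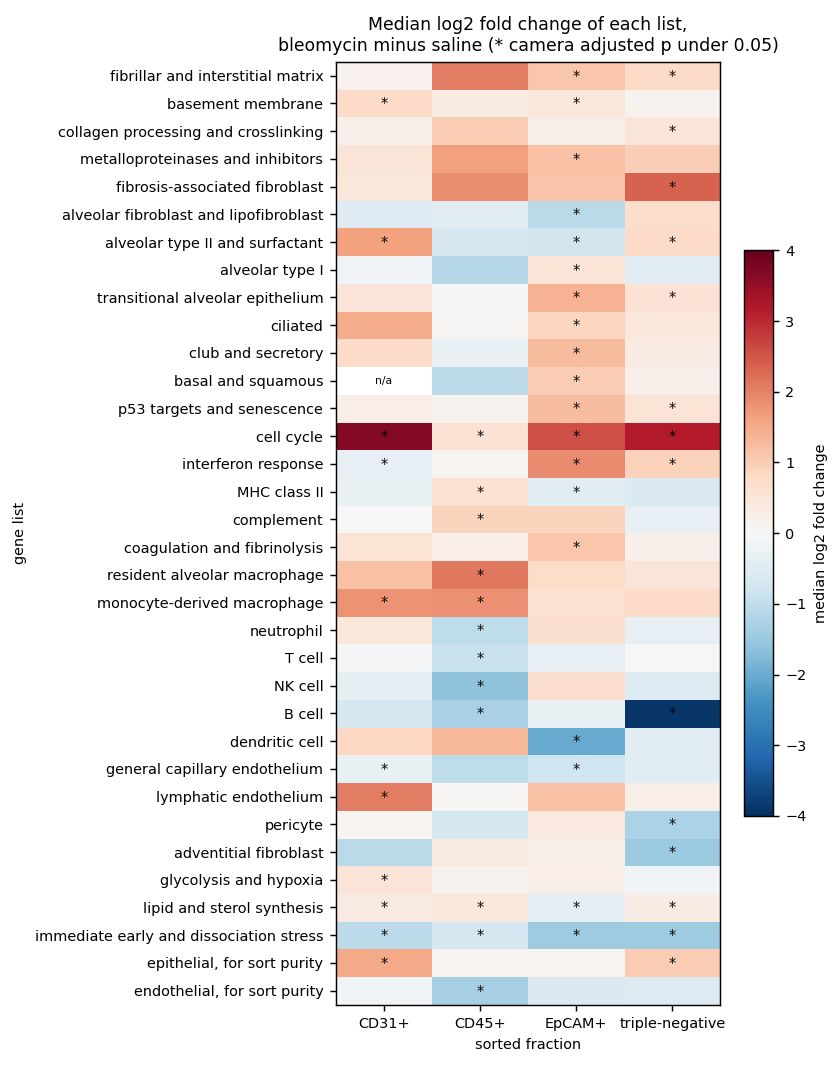
Median log2 fold change of 34 gene lists (lines) in 4 fractions (columns), with an asterisk on the 56 cells whose camera adjusted p was under 0.05 with the preset correlation. The range runs from -3.89 (B cell list, triple-negative) to 3.69 (cell cycle list, CD31+), and none of the 56 was called with an estimated correlation.

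The next question was which responses differ between fractions, tested as an interaction. The log2 changes of p53 target and interferon genes were higher in EpCAM+ than in CD31+ cells (adjusted p = 3.0e-04 and adjusted p = 0.00637 with an estimated correlation). In CD31+ cells the interferon genes fell under the preset correlation (adjusted p = 0.958 with an estimated correlation). Cell cycle genes rose more in CD31+ than in CD45+ cells under the preset correlation, but not with an estimated correlation (adjusted p = 0.987 with an estimated correlation). The effect of bleomycin differed for 12754 of 19841 genes (64.3%). In this fit Cthrc1 changed by 5.54 in triple-negative, 3.59 in CD45+, -0.69 in CD31+ and -1.46 in EpCAM+ cells (adjusted p = 1.7e-09). Tgfb1 changed by 1.58 in triple-negative cells, against 0.32 in CD31+, -0.20 in CD45+ and -0.13 in EpCAM+ cells (6.7e-15), Cdkn1a by 1.88 in EpCAM+ cells against -0.22 to 0.36 elsewhere (5.5e-09), and Mki67 by 4.42 in CD31+ cells against 0.36 in CD45+ cells (1.1e-12). The smallest p-values were those of Plekhm2, which serves lysosome transport and rose in CD45+ cells (1.61, against -0.13 to 0.08; 1.1e-21), and the death receptor gene Tnfrsf10b (2.99 in EpCAM+ and -1.45 in CD45+ cells; 1.8e-20). Changes past the threshold in opposite directions were seen for the vesicle gene Syt13 (-6.58 in CD45+ and 4.05 in triple-negative cells) and the pentraxin gene Ptx3 (3.62 in CD31+ and -2.03 in triple-negative cells). The claudin gene Cldn1 (4.30 in CD45+ and -1.20 in triple-negative cells), Cd177 (4.50 in EpCAM+ and -1.58 in CD45+ cells) and the matrix gene Vwa1 (2.93 in CD31+ and -2.27 in triple-negative cells) were others. Syt13 was not among the largest falls named from CD45+ libraries alone, which had to pass the threshold with no overlap between groups. Its fall in CD45+ cells therefore rests on the fit of all libraries and may not be shared by all of them. No difference past the threshold was found for Tnc (0.665), Postn (0.384), Vwf (0.852), Col1a1 (0.0594), Col3a1 (0.0745) or Timp1 (0.0637). This does not show equal effects. In the same fit the triple-negative rises of Col1a1 (adjusted p = 0.118) and Col3a1 (0.188) also missed the threshold, which both passed in the fit of that fraction alone.

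Between pairs of fractions, 5012 genes (CD31+ and triple-negative) to 7701 genes (CD45+ and EpCAM+) differed in effect, and in all 3727 genes were past the threshold in both directions somewhere. The correlation of log2 changes across genes, which are not independent replicates, was 0.23 for CD45+ and EpCAM+ and 0.46 for CD31+ and triple-negative cells. By list, tested between fractions after the data were seen, 27 of 29 interferon response genes had a lower log2 change in CD31+ than in EpCAM+ cells (adjusted p = 9.6e-30, and adjusted p = 0.00637 with an estimated correlation). The other 5 pairs were called under the preset correlation for this list (7.0e-16 to 0.0145), and none held (adjusted p = 0.136 to 0.987 with an estimated correlation). For p53 targets and senescence 16 of 23 were lower in CD31+ than in EpCAM+ cells (1.8e-15, and adjusted p = 3.0e-04 with an estimated correlation), 18 lower in CD45+ than in EpCAM+ cells (2.1e-09, and adjusted p = 0.00558 with an estimated correlation), and 14 higher in EpCAM+ than in triple-negative cells (5.5e-07, and adjusted p = 0.0218 with an estimated correlation). The pairs of triple-negative with CD31+ (0.00564) and CD45+ cells (0.0438) were called for p53 targets and senescence and did not hold (adjusted p = 0.609 and adjusted p = 0.987 with an estimated correlation). Of 30 cell cycle genes 29 rose more in CD31+ than in CD45+ cells (5.8e-15, and adjusted p = 0.987 with an estimated correlation), and 3 more pairs were called for this list (6.9e-09 to 9.3e-04) and did not hold (adjusted p = 0.987 for each with an estimated correlation).

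The last question was which genes change in the same direction in all 4 fractions. Of 14357 genes tested in every fraction, 905 (6.30%) were higher and 4.41% were lower in all 4, where the product of the shares gives 97.6 and 67.7 genes. The matrix and macrophage genes Spp1, Mmp12, Tnc, Fn1, Ctss, Ctsk, Clec7a and Mpeg1, the acute phase genes Serpina3n and Lrg1, and the division genes Iqgap3 and Anln were among those higher. Spp1 rose by 5.34, 8.05, 5.37 and 5.33 in CD31+, CD45+, EpCAM+ and triple-negative cells, and Tnc by 4.68, 4.73, 3.78 and 4.86. Mean Spp1 after bleomycin was 280, 4823, 113 and 3304 CPM in the same order. Mean Tnc was 93, 43, 19 and 2041 CPM, and mean Fn1 591, 5094, 412 and 15199 CPM. By the interaction test the size of the change differed for Spp1 (adjusted p = 0.00123), Fn1 (0.00153) and Mmp12 (0.00544), but not for Tnc (0.665). Carry-over of leukocyte RNA was examined in CD31+ libraries alone and stays open for the macrophage genes. Carry-over of fibroblast RNA was not tested and stays open for Tnc and Fn1, whose levels were highest in triple-negative libraries. Among those lower, the immediate early genes Atf3 (-2.46, -1.02, -2.34 and -3.33) and Nr4a1 (-1.33, -2.34, -2.43 and -2.95) stood with Nr4a3, Nfkbiz and Btg2 and with the TGF-beta pseudoreceptor gene Bambi (-1.24, -1.55, -1.65 and -1.44). The endothelial gene Clec14a (-1.28, -2.21, -1.87 and -1.12) was another, beside endothelial markers that differed by -1.31 in CD45+ and by -0.54 in EpCAM+ libraries. At an adjusted p under 0.01 the counts were 481 and 335, and with at least 2-fold changes 69 and 23. By the animal numbers of the design text the fractions share animals, so the 4 tests are not independent.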

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

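The tests of leukocyte carry-over, of the column blocks in CD31+ libraries, of a lower share of alveolar type II cells, of a few genes taking many of the counts and of the transitional genes were chosen after the result was seen. The test of the immediate early genes within column blocks was set before its own result, but the blocks had been taken up only after the data were seen. The others were not chosen after the result.

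Single libraries stood apart from the rest of their group by Dixon's test at 95%, in 34 of 362 values tested (9.39%). Chance gives about 1 in 20 for independent values with a normal spread. Single genes were tested as CPM without logs, and related genes of 1 library move together. The excess is therefore no measure of how many libraries are aberrant. Bleomycin_CD31_621 had the lowest endothelial marker mean (9.81 on the log2 scale), the highest epithelial marker mean (5.65) and an Epcam level of 18.2 CPM. In Bleomycin_CD45_613 Col1a1 reached 2348 CPM, and Bleomycin_Negative_642 had a total of 35.3 M counts. Among the named genes, Bleomycin_CD31_621 stood apart in 4, and Saline_CD31_650 and Saline_CD31_653 in 2 and 1. In CD45+ libraries it was 8 for Bleomycin_CD45_613 and 1 each for Bleomycin_CD45_616 and Saline_CD45_644, Saline_CD45_646 and Saline_CD45_647. Bleomycin_EpCAM_632 stood apart in 2 and Saline_EpCAM_654 and Saline_EpCAM_658 in 1 each, and Bleomycin_Negative_637 and Bleomycin_Negative_638 in 2 each and Bleomycin_Negative_642 and Saline_Negative_661 in 1 each.

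The effect of bleomycin differed between fractions for 12754 genes. For the genes with the smallest p-values, the largest difference in log2 fold change between any pair of fractions was 1.74 for Plekhm2, 4.44 for Tnfrsf10b, 3.18 for Slc20a1, 2.97 for Cd9, 3.41 for Fam107b, 1.97 for P2rx4, 5.24 for Vwa1, 2.97 for Ctsl, 3.24 for Slc12a2 and 3.08 for Vps37b. Among genes past the threshold in opposite directions it was 10.63 for Syt13, 7.0 for Cthrc1, 6.07 for Cd177, 5.66 for Ptx3, 6.01 for Cldn1 and 5.36 for Ccl22. Syt13 was not among the largest falls named from CD45+ libraries alone. Of the fixed genes past the threshold, Arg1 differed by 5.08, Mki67 by 4.06, Mmp12 by 3.71, Car4 by 2.99, Sftpc by 2.96, Spp1 by 2.69, Acta2 by 2.67, Epcam by 2.42, Cdkn1a by 2.10, Fn1 by 2.05, Ptprc by 1.87, Tgfb1 by 1.78 and Pecam1 by 1.37.

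Genes of the monocyte-derived macrophage list were higher in bleomycin CD31+ libraries (adjusted p = 0.958 with an estimated correlation). Against a difference between the column blocks, the list stayed called with the block as a covariate (18 rose and 1 fell, adjusted p = 0.00169), with a median over all 23 members of 1.98 within the first block and 2.36 within the second. Carry-over of leukocytes or their RNA stays open as a candidate explanation: the 100 most abundant CD45+ transcripts nearly absent from saline CD31+ libraries rose by a median of 1.94% of their CD45+ level (interquartile range 0.946 to 3.06), which is 0.536 of the median share of the list members (3.62%, 2.36 to 6.58). List members were not taken out of these 100 transcripts, so the same genes may stand on both sides of that ratio. It therefore cannot decide for or against carry-over. The share was uneven among leukocyte genes, as Lyz2 rose by 5.64% and Spp1 by 5.66% of the CD45+ level, Csf1r by 1.67%, Cx3cr1 by 1.07%, Ptprc by 0.921%, Ccr2 by 0.890%, Cd3e by 0.127% and Mmp14, a list member, by 68.9%. With the leukocyte purity covariate the list stayed called (13 rose and 2 fell, adjusted p = 0.0011) and by fry without the covariate it was not (0.0543), which leaves carry-over open, since leukocytes carried over after bleomycin would bring more macrophage RNA per cell, and a change of the endothelial cells stays open as well.

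Immediate early genes were lower after bleomycin in all 4 fractions (adjusted p = 0.712 to 0.996 with an estimated correlation). Against a difference between the column blocks, the list median was under 0 in 8 of 8 fits within blocks. Lower stress of the bleomycin lungs during dissociation and sorting stays open as a candidate explanation, since the median of the 4 heat shock genes in the list was also under 0 in all 4 fractions: -1.06 in CD31+, -1.05 in CD45+, -0.38 in EpCAM+ and -1.30 in triple-negative libraries. Of these genes 0 passed the threshold in EpCAM+ libraries, against 2, 2 and 3 in the others, and the mitochondrial share of counts was higher without overlap in bleomycin CD31+ (0.486% to 0.689% against 0.312% to 0.401%) and triple-negative libraries (0.512% to 1.23% against 0.260% to 0.474%). A lower level in the lung after bleomycin remains untested.

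Alveolar type II genes were lower and airway, alveolar type I and transitional genes higher in bleomycin EpCAM+ libraries (adjusted p = 0.712 to 0.774 with an estimated correlation). Against a few genes taking many of the counts, which would move all others by 1 common factor, 12 alveolar type II genes left after the most abundant and the surfactant genes were taken out had lower log2 changes than each of the 5 rising lists (differences -2.03 to -1.35, largest adjusted p = 0.00155 over 5 pairs, exact permutation tests). A lower share of alveolar type II cells alone may account for the mean rise of the airway and alveolar type I lists. These rose by 0.82 (alveolar type I), 0.76 (ciliated), 1.15 (club) and 0.79 (basal) with a smallest adjusted p of 0.476 over 6 pairs (exact permutation tests). A missed threshold does not show that they rose alike. Members moved apart within lists: 10 of 15 alveolar type I genes rose and 1 fell, and 9 of 11 club genes rose and 1 fell. Ager rose by 0.55 ± 0.09 (SE) and Scgb1a1 by 1.52 ± 0.25. Whether that share accounts for single members was not tested. The transitional list rose more than the alveolar type I, ciliated and basal lists (by 0.62, 0.68 and 0.65, adjusted p = 0.00622 each, exact permutation tests). Its difference from the club list (0.28) did not pass the threshold, so the largest of the 4 adjusted p was 0.340. Under the criterion of a larger rise than all 4 lists, the sources cannot be told apart. A looser criterion, 1 differing pair, was also tried after that outcome and is not used. A change of the cells after bleomycin remains open for all of these lists.

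Other splits of the libraries were counted for each comparison. Of 100 splits drawn from 792 in CD31+ libraries, 1, the real one, gave as many genes past the threshold (7838; highest other 0). Of 100 drawn from 1287 it was also 1 in CD45+ (9115; highest other 1239), EpCAM+ (10168; 4069) and triple-negative libraries (9250; 3482), and the highest other split kept 4 of the 5 saline libraries together in each of these. Of 40 regroupings of treatment within fractions, 1, the real one, gave as many genes with differing effects (12754; highest other 4852). Chance can be excluded at 1 in 20 for the counts within fractions. The regroupings of treatment take away the effect of bleomycin itself. They therefore do not show that 12754 exceeds what an equal effect in all fractions would give.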

How the results depend on the processing

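The alternatives that use the column blocks, the purity covariate in the list tests and the list counts without Bleomycin_CD31_621, Bleomycin_CD45_613, Bleomycin_EpCAM_632 and Bleomycin_Negative_642 were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Leaving out contradicted names was not run, since 0 names were contradicted.

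Counts of genes past the threshold stayed within 1.5 times their value under RLE and upper-quartile scaling, either filter, DESeq2, limma voom with quality weights, 1 fit of all groups, library sizes without 4 gene classes and the block covariate, and 0 genes were called in the opposite direction. They fell outside in these fits: in CD31+ libraries with the purity covariate 2468 higher and 2395 lower, in the first block 1678 and 1501 and in the second 2186 and 2036, in CD45+ libraries in the first block 3081 and 2603, in EpCAM+ libraries in the first block 3181 and 2958, and in triple-negative libraries in the second block 2826 and 2975. Blocks hold fewer samples; for the covariate the cause was not tested. The count of genes whose effect differs between fractions was 10913 with the strict filter, which tests fewer genes, and 12776 to 13579 otherwise (DESeq2 highest). The genes higher in all 4 fractions were 481 at an adjusted p under 0.01 and 69 with at least 2-fold changes, and those lower 335 and 23, by the stricter criterion.

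Leaving out 1 library at a time gave 3463 to 4140 higher and 3417 to 3911 lower genes in CD31+, 4256 to 4727 and 4047 to 4928 in CD45+, 4861 to 5221 and 4560 to 4944 in EpCAM+, 4307 to 4659 and 4334 to 4741 in triple-negative libraries, and 12395 to 13016 genes with differing effects.

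List calls were 0 in all 4 fractions with an estimated correlation, against 11, 12, 19 and 14 with the preset one. By fry they were 12, 19, 32 and 30, which in CD31+ libraries kept 8 of the 11 (not alveolar type II, 0.278, monocyte-derived macrophage, 0.0543, or epithelial purity, 0.181) and all elsewhere. With the purity covariate they were 8, 20, 21 and 17; the cause was not tested. Leaving out 1 library gave 6 to 14, 12 to 15, 17 to 20 and 11 to 15 calls.

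Of 3972 values of named genes under alternatives, 3800 kept their side of the threshold, 121 lost and 45 gained a call, and 6 reversed. A changed sign counted as reversed only if the main or the alternative value passed the threshold. The 3800 may therefore hold values of changed sign that passed it in neither. With the purity covariate Ptprc in CD31+ libraries was -0.39. In the first block Sftpc in CD45+ was 0.72 and Pecam1 in EpCAM+ libraries 0.11. In the second block of triple-negative libraries (3 bleomycin, 2 saline) Ager was 3.61, Vwf 1.30 and Car4 1.29. The cause was not tested. At these depths and group sizes, with a spread that was set and not estimated, 25.4% to 37.3% of simulated 1.5-fold changes were recovered.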

Other observations

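The list tests between fractions and the choice of the members named here were made after the result was seen, and no test of an explanation is reported.

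In triple-negative cells, members of 4 lists that were not called changed in both directions. Of 29 genes in chemokines and cytokines 11 fell and 7 rose (11 and 8 adjusted over the list alone), among them the neutrophil chemokine gene Cxcl1 (-3.29), the monocyte chemokine genes Ccl2 (-1.51) and Ccl7 (-2.08), and Il1b (-1.97), against rises of the interferon-induced chemokine gene Cxcl9 (2.74) and of Cxcl14 (1.66). The list as a whole was not called (adjusted p = 0.741), with its median at 0.07 and its mean at -0.48. Of 23 growth factor ligands 10 rose and 5 fell, the same adjusted over the list alone (0.277): Nrg1, Areg and Ereg, which bind receptors of the EGF family, rose by 2.51, 2.24 and 1.76, and Igf1 by 1.36, while Igf2 (-2.42) and Bmp2 (-1.81) fell. In metalloproteinases and inhibitors 9 of 15 rose and 5 fell, the same adjusted over the list alone (0.144), with the collagenase genes Mmp8 (4.73) and Mmp13 (4.52) up and the inhibitor genes Timp4 (-2.12), Timp3 (-0.76) and Timp2 (-0.65) down. In TGF-beta pathway and targets 7 of 21 rose and 8 fell, the same adjusted over the list alone (0.876): Ltbp2 (2.51) and Inhba (2.48) rose, and Tgfbi (-2.07), the co-receptor gene Tgfbr3 (-1.50) and Bambi (-1.44) fell.

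In CD45+ cells, members of the dendritic cell and unfolded protein response lists changed in both directions, and neither list was called. Of 11 dendritic cell genes 8 rose and 2 fell, the same adjusted over the list alone, with Xcr1 (3.03), Itgae (3.0) and Clec9a (1.80) up and the migration receptor gene Ccr7 (-1.44) and the plasmacytoid marker Siglech (-1.38) down. The list was not called (adjusted p = 0.0583, and adjusted p = 0.996 with an estimated correlation), but passed the threshold without any 1 of Bleomycin_CD45_613, Bleomycin_CD45_616, Bleomycin_CD45_619, Saline_CD45_644 and Saline_CD45_648 (0.033 to 0.0495). In EpCAM+ libraries 8 of 9 members fell (0.00428, and adjusted p = 0.712 with an estimated correlation), and the difference between CD45+ and EpCAM+ libraries was lost with an estimated correlation (1.9e-05, and adjusted p = 0.441 with an estimated correlation). Of 18 genes in the unfolded protein response 11 rose, among them Sdf2l1 (1.46), Pdia4 (0.97), Calr (0.80) and Xbp1 (0.53), and the transcription factor genes Atf4 (-0.83) and Ddit3 (-0.95) fell, the same adjusted over the list alone (0.0754, and adjusted p = 0.996 with an estimated correlation; 0.0418 without Bleomycin_CD45_615).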
